A study of Arabidopsis thaliana with 18 samples.

How the data were processed

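Seedlings of Arabidopsis thaliana had been kept for 4 days with shaking in 3% sucrose under 24 h of light, a condition the labels call AIC without expanding the letters. Per the labels' protocols, 1 µg of total RNA per sample went into a stranded mRNA library kit, and the libraries were sequenced strand-specifically from a single end. The 18 libraries comprised 16 insertion lines, each carrying a named allele of 1 of 6 flavonoid loci, and 2 files of the wild type Col-0. Each mutant allele had 1 library.

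The deposited values were counts per gene. Per the submitters' processing notes the reads were handled with HISAT2 and the genome build TAIR10. The counting program, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping genes and of near-identical copies, such as members of the seed albumin, small heat-shock protein and light-harvesting families, are therefore uncertain. Every file listed the same 33939 identifiers, of which 32547 were Arabidopsis locus identifiers and 1392 named small RNA features by a database number. The latter held 0.0064% to 0.0204% of the counts of a library and stayed out of library sizes and tests. No identifier belonged to the chloroplast or mitochondrial genome, so a comparison without those genes could not be run. All 32547 loci matched the annotation of TAIR10.1, which gave symbols, coordinates and gene order. Of the files, 4 had Windows line ends (both Col-0 files, tt8-8 and tt8-11) and 14 had Unix line ends. This was the one technical split visible in the files, and it was tested as a batch. Only the tt8 group held files of both kinds, and Col-0 held Windows files alone. In the fit of all groups a term for the split is therefore estimated from the tt8 libraries alone.

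Replicate files were compared before use. Over 18979 genes with a summed count of at least 20, the Col-0 files differed by less than sampling noise (chi-square per degree of freedom 0.222), whereas the other 20 pairs of libraries within a group gave values from 9.54 to 143. The Col-0 files were therefore counted as 1 sample, as the rounded mean of their counts. The design fixed before the data were examined had counted them as 2 samples, and that fit became an alternative added after seeing the data. With a single Col-0 sample, its spread was taken to be that of the other groups. Alleles of 1 locus were treated as the samples of that locus, so the spread within a group includes differences between insertion lines. Nothing in the labels says that libraries came from separate cultures, and the p-values measure only the spread between these samples.

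Genes were tested with edgeR 4.0.16 under R 4.3.3, using TMM scaling, the filterByExpr filter by group, the quasi-likelihood F-test with robust estimation of the spread (an option the fixed design had not named) and two-sided Benjamini-Hochberg adjustment at 0.05. Every adjusted p for a gene given without another tool's name comes from this test. The fit over 7 groups held 17 samples, 20747 genes and 10 residual degrees of freedom, and its TMM factors lay between 0.91 and 1.07. The comparison of regulator with enzyme mutants used 14 libraries and 19880 genes. Per-library levels are counts per 1000000 counts of the counted genes (CPM). Intervals on single CPM values are exact 95% Poisson intervals, 0 counts are given with a floor of 3 counts, and both cover counting error only. Total counts ran from 8057534 in ttg1-24 to 27145377 in tt3-4, so 3 counts correspond to 0.372 CPM in the shallowest library.

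Before the data were examined, 21 gene lists with 223 members, all of them in the files, were fixed for flavonoid, phenylpropanoid, epidermal, stress, hormone, nutrient and seed genes. The 18 lists with at least 5 tested members in a comparison were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, all in limma 3.58.1 on voom values, and adjusted over the lists within a comparison. An adjusted p given for a list without another name is from camera at the preset correlation. None of the 36 list calls held with an estimated correlation. With fry, few lists had an adjusted p under 0.05 in a comparison. These were the lignin list in tt8 (0.033), tt3 (0.0405) and tt1 (0.0443) and the seed storage list in tt1 (0.045), all against Col-0. For the late anthocyanin list in ttg1 against Col-0 the fry adjusted p was 0.326. Members past the threshold were counted over all genes tested and again adjusted over the list alone.

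The genes named in the text follow a rule fixed before the data were examined. It takes the 6 targeted loci, the members of the early flavonoid, late anthocyanin and flavonoid regulator lists, up to 4 members of each other list past the threshold for the tt8, ttg1 and regulator comparisons, and the genes with the largest called rise and fall (6 each way for tt8, ttg1 and the regulator comparison, 4 each way otherwise). The last part requires a mean of at least 1 CPM, no overlap between the sides compared and a symbol. It also takes genes low in 1 library alone, defined as a level under 5% of the median of the other samples where that median was at least 5 CPM and every other sample exceeded 25% of it. Any other gene named was chosen after its values were seen. Of the genes named by the rule and called in a comparison, CCR1, MEE23, CYP86A2, GSTF2, EMB2788, PGIP1 and GSTF12 overlap a gene on the opposite strand, so their levels are less certain. The other named genes were not checked one by one for such overlap.

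The procedure was tested on simulated counts drawn from the means and sizes of these libraries. For tt8 against Col-0 it recovered 4.5% of genes changed 2-fold, 65.7% of those changed 4-fold and 83.3% of those changed 8-fold, with 6 false calls among 20747 genes. For ttg1 against Col-0 the shares were 1.5%, 53.7% and 75.8%, with 3 false calls. For tt8 against ttg1 they were 34.3%, 82.1% and 92.4%, with 4 false calls, and for regulators against enzymes 65.7%, 91% and 98.5%, with 7 false calls. DESeq2 made 32 to 56 false calls on the same simulated counts. Apart from the planted changes, each gene was drawn independently around 1 mean common to all samples. The simulation thus lacks differences shared across genes, such as those that part the real libraries. Its recovered shares and false calls do not carry over to the real comparisons.

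Alternatives changed 1 choice at a time: RLE size factors, no filter, a stricter filter, a fit of the compared libraries alone, counts thinned to the shallowest library, the line-end split as a term or 1 side of it alone, DESeq2 1.42.0, and each library left out in turn. The Col-0 files as 2 samples and 1 surrogate variable (sva 3.50.0) were added after seeing the data. Principal components used log2(CPM + 0.5) of 18694 genes.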

Results

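The series profiled seedlings of putative transparent testa (tt) mutants and asked which transcripts differ between the mutants and the wild type Col-0 under AIC. The mutated loci act in flavonoid synthesis, the pathway that gives flavonols, red anthocyanins and the brown tannins of the seed coat. The loci BAN (anthocyanidin reductase), TT3 (dihydroflavonol reductase, DFR) and TT5 (chalcone isomerase, CHI) encode enzymes. TT8 (a bHLH protein) and TTG1 (a WD40 protein) are partners in the regulatory MYB-bHLH-WD40 complex, and TT1 encodes a zinc finger protein. There were 6 alleles of tt8 and 2 alleles each of ban, tt1, tt3, tt5 and ttg1. The total count was 13082798 and 15974040 in ban-6 and ban-7, 18523380 and 13076113 in tt1-4 and tt1-5, 18724321 and 27145377 in tt3-3 and tt3-4, and 22669572 and 20656936 in tt5-3 and tt5-4. It was 14134589, 13766935, 18146427, 22746917, 21081651 and 24387446 in tt8-7 to tt8-12 in numerical order, 26961420 and 8057534 in ttg1-23 and ttg1-24, and 16185800 and 15906406 in the Col-0 files.

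The Col-0 files differed by less than the sampling noise, with a correlation of log2 CPM across genes of 0.9994, and were counted as 1 sample. Each Col-0 level below is therefore the level of that sample. This sample stood apart from the mutants: at 135 genes it lay at least 2-fold below every mutant library and at 28 genes at least 2-fold above, while the number of genes at which a mutant library stood apart in this way ranged from 0 in tt8-8 and tt8-11 to 172 in ttg1-24. The genes high in Col-0 included GPAT5 (AT3G11430), CYP86A1 (AT5G58860), CYP86A2 (AT4G00360) and ABCG20 (AT3G53510). CYP86A1 stood at 175 CPM in Col-0 and at 36.3 to 75.8 CPM in the mutants. Genes low in Col-0 included PMEI2 (AT3G17220), a pectin methylesterase inhibitor, at 4.18 CPM against 16.3 to 43.3 CPM, and RCI2B (AT3G05890), a small membrane protein induced by cold, at 11.6 CPM against 64.8 to 177 CPM. Among genes named below, PELPK1, ABCG23 and ALMT12 also stood apart as high in Col-0, and PGIP1, EMB2788, ARV1 and NF-YC12 as low. Only genes with the highest levels on each side were examined by name, so others named below may stand apart too. Such genes entered every comparison with Col-0, so their rise or fall in 1 comparison is not particular to that locus. Counting the Col-0 files as 2 samples raised the number of genes called in these comparisons to between 865 and 4347.

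Libraries of 1 locus also differed widely from each other. The first principal component carried 47.8% of the variance among the 17 samples and parted alleles of the same locus: ban-6 lay at −68.9, close to Col-0 at −61.8, and ban-7 at 72.1, while the libraries labelled tt8 ran from −36.7 in tt8-8 to 53.1 in tt8-9. Genes at its high end, named after their values were seen, included the oil body protein gene OLEO1 (12.2 CPM in ban-6, 53.7 in Col-0, 812 in ban-7) and the beta-glucosidase gene BGLU19 (1.45, 3.43 and 453 CPM). At its low end the vacuolar water channel gene GAMMA-TIP was at 263 CPM in ban-6 and in Col-0 and at 3.88 CPM in ban-7, and the sugar transporter gene SWEET12 at 115, 58.5 and 1.13 CPM. This spread within a locus is part of the error of every comparison.

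**Figure D1:**
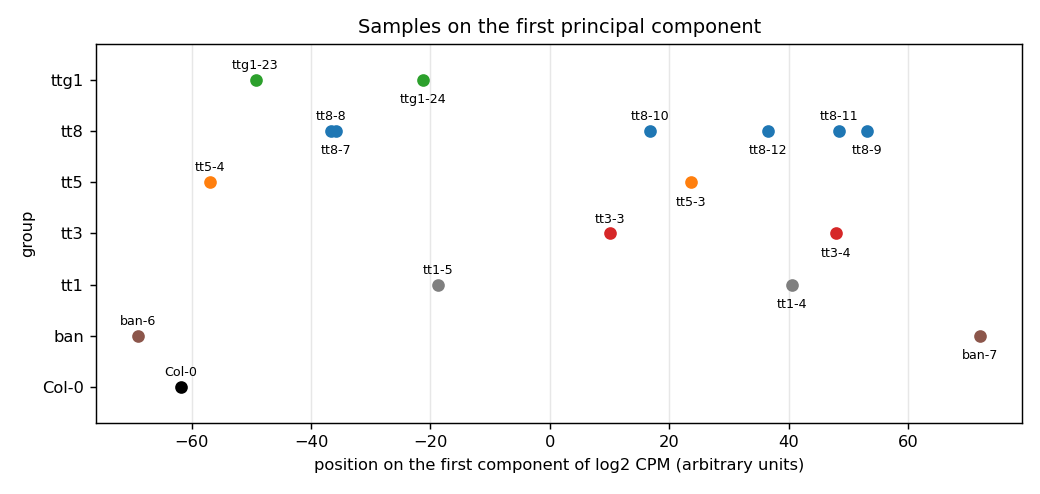
Position of the 17 samples on the first principal component of log2 CPM (horizontal axis, arbitrary units) by group (vertical axis), where each point is 1 sample. The alleles of ban lie at opposite ends (−68.9 and 72.1) and those labelled tt8 spread from −36.7 to 53.1.

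Each targeted locus was examined in every library. TTG1 (AT5G24520, chromosome 5, 8370317 to 8372847 of TAIR10.1) had 0 counts in ttg1-24, which allows up to 0.372 CPM, and 15.9 CPM (95% interval 14.4 to 17.5) in ttg1-23, against 30.4 CPM in Col-0 and 22.7 to 28.6 CPM in the other mutants. TT5 (AT3G55120, chromosome 3, 20430059 to 20431597) was at 4.23 and 4.50 CPM in tt5-3 and tt5-4 against 43.4 CPM in Col-0. TT3 (AT5G42800, chromosome 5, 17164093 to 17166032) was not lower in the libraries labelled tt3, at 211 and 274 CPM against 63.2 CPM in Col-0. TT8 (AT4G09820, chromosome 4, 6181881 to 6186523) ranged widely in the libraries labelled tt8: it was at 28.7 CPM in tt8-7, 102 in tt8-8, 8.49 in tt8-9, 73.0 in tt8-10, 6.97 in tt8-11 and 40.1 in tt8-12, against 11.5 CPM in Col-0 and 10.2 to 36.9 CPM in the libraries of ban, tt1, tt3 and tt5. A count over a whole gene need not fall when an insertion interrupts it, so these levels do not check the tt3 and tt8 labels. The deposited files of the 16 mutant libraries bear short names that differ from the allele, the one for ban-6 resembling the gene symbol HEMA1. Which line a library comes from therefore rests on its title alone. As to the locus, the low TT5 levels in tt5-3 and tt5-4 and the 0 counts of TTG1 in ttg1-24 go with their titles. In ban-6, HEMA1 was at 46.3 CPM, within the range of the other samples (41.7 to 134). The low gene there was HEMA2, at 10.2 CPM (other samples 52.7 to 369). BAN (AT1G61720, chromosome 1, 22790966 to 22792803) and TT1 (AT1G34790, chromosome 1, 12763902 to 12765686) had at most 2 and 1 counts in any library, and neither could be compared at this depth.

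**Figure D2:**
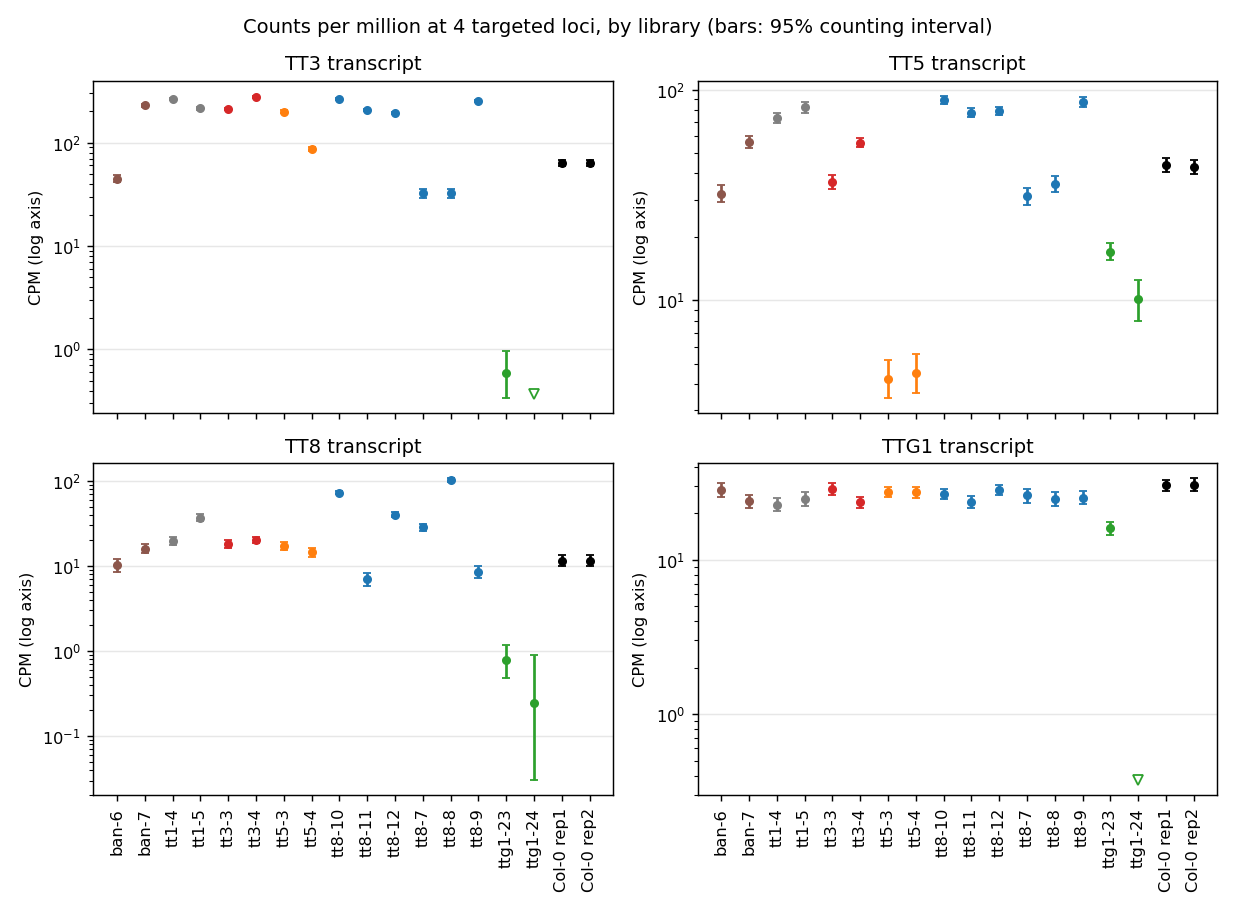
Levels in CPM of the TT3, TT5, TT8 and TTG1 transcripts (log axis) in each of the 18 libraries, coloured by group, with 95% Poisson intervals as bars and an open triangle at the 3-count floor where the count was 0. TT5 is low in both tt5 libraries (4.23 and 4.50 CPM) and TTG1 is at 0 counts in ttg1-24, while TT3 and TT8 are not low throughout the libraries named after them.

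The comparison of ttg1 with Col-0 asked how transcripts differ in lines of the WD40 regulator. Of 11 late anthocyanin genes, which turn dihydroflavonols into anthocyanins and decorate and transport them, 5 were called lower. LDOX (AT4G22880), the anthocyanidin synthase, was at 0.260 and 0.124 CPM in the ttg1 libraries against 39.8 CPM in Col-0 (log2 fold change −7.52 ± 1.27 SE, adjusted p = 0.0221). The anthocyanin glycosyltransferase UGT79B1 (AT5G54060) fell by 7.40 (adjusted p = 0.0144), the glutathione transferase GSTF12 (AT5G17220), which anthocyanin transport requires, by 7.40 ± 1.22 (adjusted p = 0.0201) on the log2 scale, and DFR stood at −7.32 ± 1.49 (adjusted p = 0.0362). The malonyltransferase 5MAT (AT3G29590) fell by 5.12 ± 0.82 (adjusted p = 0.0185). Of the 11 late genes tested, these 5 were lower, 7 were lower when adjusted over the list alone, and the median log2 fold change was −4.60 (adjusted p = 1.28e-03, and adjusted p = 0.682 with an estimated correlation). UGT75C1 missed the threshold at −4.60 (adjusted p = 0.0586), as did 3AT1 at −2.64 (adjusted p = 0.0659), while BGLU10 was at 0.61 (adjusted p = 0.418).

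Of the 6 early flavonoid genes, which lead from chalcone synthesis to flavonols and dihydroflavonols, 0 passed the threshold in ttg1 in edgeR, 1 had an unadjusted p under 0.05 and 1 was called by DESeq2. CHS was at 90.2 and 275 CPM in the ttg1 libraries against 347 CPM (adjusted p = 0.612), and F3'H stood at −2.27 (SE 1.12) on the log2 scale. Of 15 flavonoid regulator genes 0 were called in edgeR, 3 had an unadjusted p under 0.05 and DESeq2 called 2 (list median −0.47, adjusted p = 0.227). TT8 stood at −4.31 (SE 1.38, adjusted p = 0.122), with 21 counts in ttg1-23 and 2 in ttg1-24, and the MYB activator PAP1 at 0.45 (SE 0.56). TTG2 (AT2G37260), a WRKY factor of trichome and seed coat development, fell by 2.09 ± 0.33 (adjusted p = 0.0181), to 5.19 and 3.60 CPM from 18.4 CPM. The anion channel ALMT12 fell by 2.70, the late embryogenesis gene EM1 by 1.62 and the low-oxygen factor LBD41 by 1.33 on the log2 scale. The list of abscisic acid and cold genes was lower as a list (9 of 9 fitted values below 0, median −1.17, adjusted p = 4.14e-03, and adjusted p = 0.682 with an estimated correlation). The largest rises by the naming rule were RCI2B at 3.41, PMEI2 at 3.26, the ubiquitin-conjugating enzyme variant MMZ2 at 3.23, the polygalacturonase inhibitor PGIP1 at 2.96, the peptide gene RGF5 at 2.79 and the glutathione transferase GSTF2 at 2.77. At GSTF2, ttg1-24 stood above every other sample (273 CPM, others 29.4 to 133). In ttg1-24 the neighbours AT5G24490, AT5G24500 and DMR6 of TTG1 were nearly absent too. A change seen mainly in that library can therefore not be assigned to TTG1 alone. In all, 323 of 20747 genes changed (196 higher, 127 lower) and 3929 had an unadjusted p under 0.05. Without ttg1-24 the number fell to 30, and without either ttg1 library, with the line-end split as a term (14 genes in all) or with the compared libraries alone (0 genes in all) none of the 11 late genes passed the threshold in edgeR, with LDOX at −8.20 (adjusted p = 0.0718) without ttg1-23 and at −7.35 (adjusted p = 0.121) without ttg1-24.

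**Figure D3:**
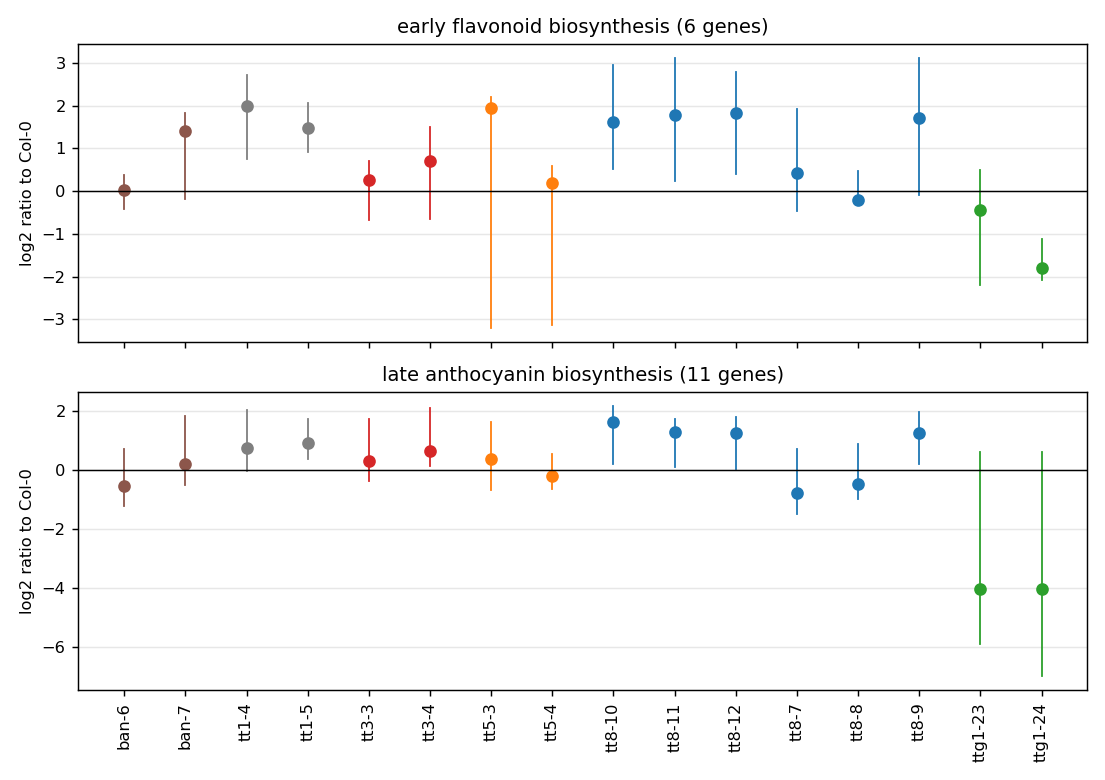
Log2 ratio of CPM to Col-0 (pseudocount 0.5 CPM) for the 6 early flavonoid genes (top) and the 11 late anthocyanin genes (bottom) in each of the 16 mutant libraries, where points are list medians and lines run from the lowest to the highest member. The late list lies at −4.04 in both ttg1 libraries and between −0.76 and 1.63 in the others.

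The libraries labelled tt8 were compared with Col-0 to ask the same of the bHLH regulator. No flavonoid gene of either list passed the threshold: 0 of 11 late genes (1 at an unadjusted p under 0.05) and 0 of 6 early genes (0 at an unadjusted p under 0.05) were called in edgeR, and 0 of either list in DESeq2. The medians were 0.86 for the late list (adjusted p = 0.241) and 1.44 for the early list (adjusted p = 0.113). LDOX was at 108 ± 64.7 CPM (SD, n = 6) against 39.8 CPM, and CHS at 1241 ± 534 CPM against 347 CPM. The list of lignin and sinapate ester genes was lower (median −0.54, 11 of 12 fitted values below 0, adjusted p = 0.0119, and adjusted p = 0.516 with an estimated correlation). Its 1 called member, the lignin enzyme CCR1, fell by 1.81 ± 0.32 (adjusted p = 0.0181). The methyltransferase OMT1, which acts on flavonols, fell by 1.63 ± 0.38 (adjusted p = 0.0476) and LBD41 by 1.08 ± 0.23 (adjusted p = 0.0351). The photosynthesis list was lower too (mean −0.91, 15 of 16 below 0, 1 member at an unadjusted p under 0.05 and 0 called in edgeR or DESeq2, adjusted p = 0.0119, and adjusted p = 0.735 with an estimated correlation).

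Among the largest called falls in the libraries labelled tt8, GPAT5 fell by 2.05, the cell wall protein PELPK1 by 2.18, the monolignol glucosyltransferase UGT72E2 by 2.25 and the root patterning factor MGP by 2.92 on the log2 scale. The transporter ABCG23 was at 6.55 ± 2.07 CPM (SD, n = 6) against 26.5 CPM in Col-0, and ALMT12 at 3.65 ± 1.40 against 14.8 CPM. The rises were led by RCI2B at 3.23, PMEI2 at 3.00, RGF5 at 2.69, the small RNA precursor TAS2 at 2.68 and PGIP1 at 2.67. Of 20747 genes 458 changed (299 higher, 159 lower), and 4246 had an unadjusted p under 0.05. The line-end term left 34 genes and the files with Windows line ends alone 0. The compared libraries alone gave 212 higher and 342 lower. Leaving out tt8-9, tt8-10, tt8-11 or tt8-12 lowered the number to 254, 265, 261 and 261.

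Setting tt8 directly against ttg1 compares no Col-0 level, but the fit takes its spread from all groups. With the tt8 and ttg1 libraries fitted alone 0 genes passed, and with the Col-0 files as 2 samples 95 did. Of 20747 genes 9 differed (7 higher and 2 lower in tt8), and 2946 had an unadjusted p under 0.05. LDOX was higher in the libraries labelled tt8 by 8.87 ± 1.21, GSTF12 by 8.26 ± 1.15, UGT79B1 by 8.15 ± 1.02 and 5MAT by 6.18 ± 0.75 on the log2 scale (adjusted p from 0.0161 to 0.0222), with every tt8 library above both ttg1 libraries. TTG2 was higher by 2.56 ± 0.26 (adjusted p = 7.32e-03). The other called genes were AT4G04750 at 4.06, AT3G14880 at 1.68, AT3G61198 at −2.23 and AT3G57950 at −2.85, which have no symbol and were named after their values were seen. Of the late list 4 of 11 members were called, 10 when adjusted over the list alone, and its median was 5.74 (adjusted p = 1.44e-06, and adjusted p = 0.411 with an estimated correlation). Of the early list 0 of 6 passed over all genes in edgeR, 6 when adjusted over the list alone and 5 in DESeq2, with a median of 2.29 (adjusted p = 4.73e-06, and adjusted p = 0.410 with an estimated correlation). Root hair genes were lower in tt8 as a list (12 of 13 fitted values below 0, median −0.94, adjusted p = 2.27e-03, and adjusted p = 0.594 with an estimated correlation), as were photosynthesis genes (median −0.47, adjusted p = 0.0225, and adjusted p = 0.620 with an estimated correlation). The abscisic acid and cold list (median 0.85, adjusted p = 2.27e-03) and the seed storage list (median 1.28, adjusted p = 6.02e-03) were higher, with adjusted p = 0.411 and 0.594 with an estimated correlation. Relative to Col-0, the abscisic acid and cold median was −0.92 in ttg1-23 and −1.26 in ttg1-24. It was lower still in tt8-11 (−1.28) and tt8-12 (−1.44), and higher in tt8-7, tt8-8, tt8-9 and tt8-10 (−0.65 to 0.28). The number of genes called was 311 without tt8-7, 174 without ttg1-23 (25 higher and 149 lower in tt8), 5 without tt8-9 and 0 without ttg1-24, where the fit of tt8 against a lone ttg1 library borrows its spread from the other groups. DESeq2 called 624.

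In the libraries labelled tt3, in which the TT3 transcript was not lower, 125 genes differed from Col-0 (80.8% higher, 24 lower, 3892 at an unadjusted p under 0.05). PMEI2 rose by 2.70 ± 0.50, LAP3 by 2.46 ± 0.49, the factor WRKY50 by 2.06 ± 0.33 and the sterol homeostasis gene ARV2 by 1.97 ± 0.21 on the log2 scale. CYP86A2 fell by 2.16 ± 0.29, MEE23 by 1.87 ± 0.33, GPAT5 by 1.77 ± 0.33 and the pectin methylesterase PME2 by 1.63 ± 0.32. The heat shock list was higher (10 of 10 fitted values above 0, median 3.24, 0 called over all genes in edgeR, 7 in DESeq2 and 7 adjusted over the list alone, adjusted p = 2.03e-03, and adjusted p = 0.482 with an estimated correlation). The small heat shock gene HSP17.6II was at 76.9 CPM in tt3-3 and 28.8 in tt3-4 against 3.43 CPM in Col-0. The lignin list (median −0.74, adjusted p = 7.70e-03), the photosynthesis list (median −0.90, adjusted p = 9.24e-03, with −0.25 in tt3-3 and −1.06 in tt3-4) and the low-oxygen list (median −0.59, adjusted p = 0.0220) were lower, with adjusted p = 0.482, 0.558 and 0.482 with an estimated correlation. Of the late anthocyanin genes 0 of 11 were called in edgeR or DESeq2, and 0 had an unadjusted p under 0.05 (median 0.36). Without tt3-3 the number of genes fell to 23, without tt3-4 to 34 and with the line-end term to 10. The compared libraries alone gave 489 genes, 41.9% of them higher and 25 shared with the 125.

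In the tt5 libraries, mutants of chalcone isomerase, 51 genes differed from Col-0 (48 higher, 3 lower, 2243 at an unadjusted p under 0.05). CHI itself fell by 3.42 ± 0.57 (adjusted p = 0.0314) and CYP86A2 by 1.62 ± 0.29 on the log2 scale, and the transporter ABCG20 was at 34.4 and 35.0 CPM against 79.2 CPM (adjusted p = 0.0434). WRKY50 rose by 2.04 ± 0.33, ARV2 by 1.76 ± 0.21, ARV1 by 1.71 ± 0.17 and NF-YC12 by 1.68 ± 0.30. At ARV1 and NF-YC12 the Col-0 sample lay at least 2-fold below every mutant library, not only those of tt5. WRKY50 and ARV2 also rose against Col-0 in the libraries labelled tt3 and ban, so their rises are not particular to tt5 either. The heat shock list was higher (median 2.38, 10 of 10 fitted values above 0, adjusted p = 1.62e-03), and the photosynthesis list (median −0.60, adjusted p = 1.62e-03, but a median ratio to Col-0 of −1.15 in tt5-3 and 0.05 in tt5-4), the phosphate and nitrate list (median −0.41, adjusted p = 0.0254) and the lignin list (median −0.54, adjusted p = 0.0260, with −0.12 in tt5-3 and −0.53 in tt5-4) were lower, each with adjusted p = 0.628 with an estimated correlation. Late anthocyanin genes had a median of 0.07, with 0 of 11 called in edgeR or DESeq2 and 0 at an unadjusted p under 0.05. The number of genes was 12 with the line-end term, 0 with the compared libraries alone, 19 without tt5-3 and 25 without tt5-4. With those libraries left out CHI stood at −3.36 (adjusted p = 0.200) and −3.48 (adjusted p = 0.186).

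In the libraries labelled tt1, whose target could not be checked either, the seed storage and maturation list was higher (12 of 12 fitted values above 0, median 4.17, 0 called over all genes in edgeR, 8 in DESeq2 and 8 adjusted over the list alone, adjusted p = 1.03e-06, and adjusted p = 0.342 with an estimated correlation). The storage protein gene CRA1 was at 6643 CPM in tt1-4 and 1148 in tt1-5 against 55.3 CPM in Col-0, and CRC at 6182 and 1110 against 56.6 CPM. The early flavonoid list was higher (median 1.53, 6 of 6 above 0, adjusted p = 0.0198, and adjusted p = 0.423 with an estimated correlation). The late anthocyanin list had a median of 0.67, with 0 of 11 genes called in edgeR or DESeq2 and 0 at an unadjusted p under 0.05. Photosynthesis genes were lower as a list (median −1.61, 16 of 16 below 0, adjusted p = 6.61e-05, and adjusted p = 0.408 with an estimated correlation), as were the lignin (median −0.71), phosphate and nitrate (median −0.79), general phenylpropanoid (mean −0.89) and low-oxygen (median −0.29) lists, each with adjusted p = 0.342 with an estimated correlation. The low-oxygen median ratio to Col-0 was 0.01 in tt1-4 and −0.47 in tt1-5, so only tt1-5 was lower by this measure. Among single genes, RCI2B rose by 3.21 ± 0.72, PGIP1 by 3.02 ± 0.54, TAS2 by 2.91 ± 0.57 and PMEI2 by 2.53 ± 0.50 on the log2 scale. The xylem gene TED6 fell by 3.42 ± 0.58, GPAT7 by 2.67 ± 0.43, CYP705A2 by 2.44 ± 0.54 and CYP86A2 by 2.43 ± 0.29. In all 322 genes changed (241 higher, 81 lower, 3517 at an unadjusted p under 0.05). There were 52 left without tt1-4, 22 with the line-end term and 0 with the compared libraries alone.

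In the libraries labelled ban, whose target could not be checked, 118 genes differed from Col-0 (99 higher, 19 lower, 3103 at an unadjusted p under 0.05). PMEI2 rose by 2.69 ± 0.50, EMB2788 by 1.95 ± 0.32, WRKY50 by 1.94 ± 0.33 and ARV2 by 1.91 ± 0.21 on the log2 scale. PELPK1 fell by 1.97 ± 0.35, GPAT5 by 1.83 ± 0.33, CYP86A1 by 1.74 ± 0.30 and CYP86A2 by 1.62 ± 0.29. The lists of photosynthesis (median −0.69, adjusted p = 2.88e-03, but a median ratio to Col-0 of −0.11 in ban-6 and −1.65 in ban-7), jasmonate (median −1.05, adjusted p = 2.88e-03), phosphate and nitrate (median −0.54), lignin (median −0.53), general phenylpropanoid (median −0.81, with −0.53 in ban-6 and −1.61 in ban-7), cell division (median −0.88, with −0.44 and −1.52) and sugar response genes (median −0.86, with −0.18 and −1.53) were lower, with adjusted p = 0.495 for photosynthesis and 0.443 for the others with an estimated correlation. The late anthocyanin list had a median of −0.14, and 0 of its 11 genes were called in edgeR or DESeq2 or had an unadjusted p under 0.05. The ban libraries differed from each other more than any other pair within a group (chi-square per degree of freedom 143). The number of genes was 932 without ban-6, 26 without ban-7, 14 with the line-end term and 0 with the compared libraries alone. Of the 11 list calls in comparisons that include ban, 5 were lost without ban-7 and 3 without ban-6.

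Libraries labelled as regulator mutants (tt8 and ttg1, 8 libraries) were set against those labelled as enzyme mutants (ban, tt3 and tt5, 6 libraries). TT8 was above Col-0 in 4 of the 6 tt8 libraries, TT3 was above it in both tt3 libraries and BAN could not be checked, so the losses are not established and an absence of calls does not show that they act alike. No gene of 19880 passed the threshold in edgeR, 884 had an unadjusted p under 0.05, and DESeq2 called 1, AT5G02940 (11.7 ± 3.90 CPM against 5.05 ± 1.38, log2 fold change 1.27, adjusted p = 4.18e-03 in DESeq2), a gene named after its values were seen. PAP1, an activator of anthocyanin genes, stood at 1.01 ± 0.27 (13.7 against 7.03 CPM, unadjusted p = 2.43e-03, not past the threshold over all genes) and DFR at −0.50 ± 0.98 (adjusted p = 0.977). As lists, root hair genes were lower in the regulator libraries (11 of 11 fitted values below 0, median −1.03, adjusted p = 2.42e-03) and heat shock genes were lower (median −0.47, adjusted p = 9.36e-03). Single enzyme libraries weigh on both. The root hair median relative to Col-0 was highest in ban-6, with 0.92 in tt5-4 and 0.59 in tt5-3. It was −0.22, −0.72 and −0.41 in ban-7, tt3-3 and tt3-4, below the 0.55 of ttg1-23. The heat shock median was 3.70 in tt3-3 but 0.70 in ban-7, against 2.67 in tt8-7. Low-oxygen genes (median 0.25, adjusted p = 3.48e-03) and jasmonate genes (median 0.30, adjusted p = 3.95e-03) were higher, and all 4 lists had adjusted p = 0.988 with an estimated correlation. Here too the sides overlapped. The low-oxygen median relative to Col-0 was 0.31 in tt5-3 but −0.52 in tt3-3, against −0.1 in tt8-8 to 0.4 in ttg1-23. The jasmonate median was 0.08 in tt3-3 but −1.22 in ban-6, against −0.7 in tt8-9 to 0.08 in tt8-11.

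Allele by allele, with 1 library each and no test, the median log2 ratio of the late anthocyanin list to Col-0 was −4.04 in both ttg1-23 and ttg1-24. Among the libraries labelled tt8 it was −0.76 in tt8-7 and −0.46 in tt8-8, but 1.25 in tt8-9, 1.63 in tt8-10, 1.31 in tt8-11 and 1.26 in tt8-12. It was −0.53 in ban-6 and 0.23 in ban-7, 0.77 and 0.94 in the tt1 libraries, 0.33 and 0.64 in the tt3 libraries, and 0.37 in tt5-3 and −0.20 in tt5-4. The median of the early list ranged from −1.79 in ttg1-24 to 1.99 in tt1-4. The general phenylpropanoid and lignin lists had medians below Col-0 in 16 of 16 mutant libraries and the heat shock list had a median above it in 16 of 16, and all of these ratios share the 1 Col-0 sample.

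Genes lost from 1 library alone were counted to look for deletions or interrupted genes. By the rule, 11 genes were low in 1 library alone, and 12 samples had none. In ttg1-24 the rule took 4 genes in a run from 8365601 to 8383401 on chromosome 5 (17.8 kb), namely AT5G24490, AT5G24500, TTG1 and the oxygenase gene DMR6. DMR6 was at 0.124 CPM against a median of 30.1 in the other samples, and AT5G24500 at 0 counts against 21.9 CPM. The expressed neighbours outside the run were present, PRR5 at 154 CPM against 88.8 and AT5G24570 at 6.33 CPM against 10.1. In tt1-5 the adjacent genes AT1G55805 (0 counts, other samples 13.2 CPM) and UKL3 (0.306 against 29.0 CPM), on chromosome 1 far from TT1, were low. The rule also took AT1G35780 in tt8-10 (1.06 against 24.7 CPM), the bHLH factor IBH1 (0.229 against 13.0 CPM) and the adjacent seed albumin genes 2S3 (17 counts, median of the others 30.7 CPM) and 2S4 (0.153 against 7.19 CPM) in ban-6, and AT1G74453 in Col-0 (0.187 against 6.27 CPM). In ban-6 all 12 seed storage and maturation genes were below Col-0 (median log2 ratio −1.46), so the low 2S3 and 2S4 need not mark a lost stretch.

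**Figure D4:**
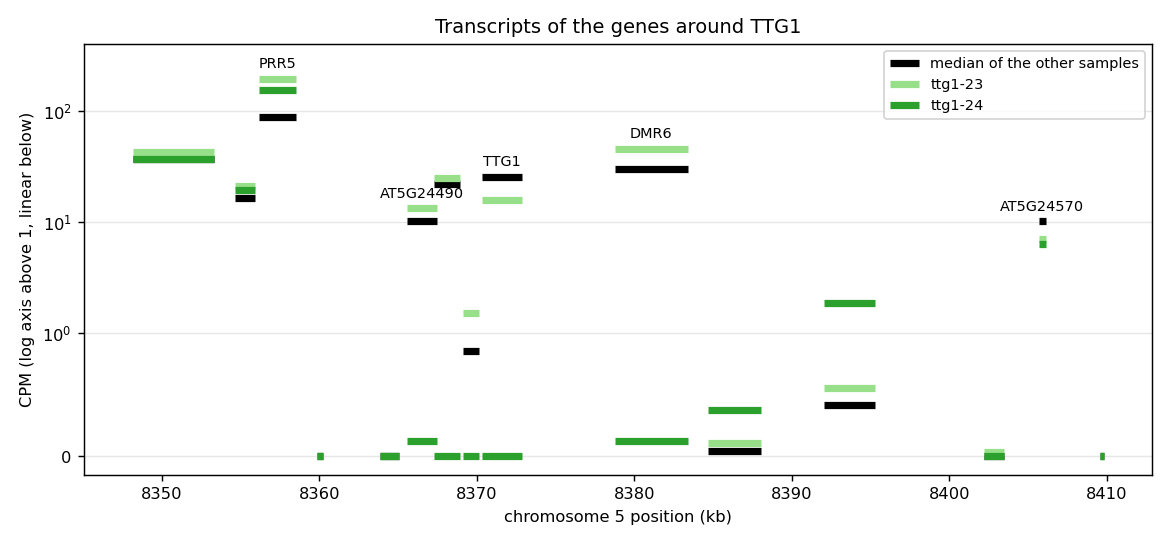
Genes around TTG1 on chromosome 5 (horizontal axis, kb in TAIR10.1) drawn to scale at their level in CPM (vertical axis, logarithmic above 1 CPM) for ttg1-24, ttg1-23 and the median of the other samples. The genes from AT5G24490 to DMR6 lie at 0 to 0.124 CPM in ttg1-24, while PRR5 stands at 154 CPM and AT5G24570 at 6.33 CPM.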

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

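The tests of line ends at genes taken without tt8-8 and tt8-11, of the line-end split, the locus and seed transcripts on the first component, both tests of the TT8 level, and the splits of the libraries were chosen after the results were seen, while the tests of overlapping genes, line ends and thinning at the Col-0 genes and of depth on the first component were written before theirs.

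Col-0 stood at least 2-fold beyond every mutant library at 163 genes, and 22.2% of those low in Col-0 were not protein-coding, against 2.23% of all tested genes. Line ends as the mark of a processing batch did not account for most of this: at the 173 genes where Col-0 stood as far beyond the 14 libraries with Unix line ends, taken without regard to tt8-8 and tt8-11, these 2 lay toward Col-0 by a median of 0.065 of the gap (95% interval 0.047 to 0.08), the highest of 15 pairs of tt8 libraries, where a batch predicted at least 0.5, and the 0.057 at the 163 genes decides nothing because their choice bounds it. Thinning every library to the 8057534 counts of ttg1-24 left 0.969 of the genes, so low counts did not account for it either. A different assignment of reads of overlapping genes in the Col-0 files could not be settled, because 31.9% of the genes low in Col-0 overlap a gene on the opposite strand (95% interval 24.1% to 40.4%) against 26.8% of all tested genes, 1.19 times as many, and the interval reaches past the bound set for excluding it. A difference shared by all mutant lines, such as handling apart from Col-0, cannot be told apart from mutation, since there is 1 Col-0 sample.

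The first component parted alleles of the same locus. Depth did not account for it, as the component kept 0.954 of its share of variance after thinning. The 3 samples from files with Windows line ends lay on both sides of the median of the others (exact permutation test, two-sided p = 0.515). The mutated locus explained 19.4% of the variance of the mutant libraries along it, below the median of 32.2% for random assignments (permutation p = 0.789). The collection of insertion lines was not tested. The SAIL line lay above the SALK line in ban (72.1 and −68.9), tt5 (23.7 and −56.9) and ttg1 (−21.2 and −49.3). SALK lines of the same locus also parted, with tt1-4 at 40.6 and tt1-5 at −18.8, and tt8-9 at 53.1 and tt8-8 at −36.7. The degree to which seed transcripts remain may contribute. Over 17 samples the seed storage and maturation median had r = 0.47 with the component built without its genes (permutation p = 0.056, adjusted over 2 relations 0.056). The rho was 0.63 (permutation p = 0.0073), but r was 0.31 without ban-6 and Col-0, so the relation rests in part on those samples and stays open. The permutations shuffled samples and compared no random lists, so they do not single out seed genes.

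TT8 transcript was above the range of the 9 samples of Col-0, ban, tt1, tt3 and tt5 in 3 of the 6 libraries labelled tt8 and below it in 2. Reads of related bHLH genes counted at TT8 did not account for the level, since TT8 in ttg1 was at most 0.068 of its Col-0 level while EGL3 kept at least 0.803 of its own and GL3, which fell too, 0.261 to 0.459, and in tt8-8 TT8 was at 102 CPM with EGL3 at 2.32 and GL3 at 2.91 CPM. Against the range of 10.2 to 36.9 CPM, 5 of the 6 lay outside and tt8-7 at 28.7 CPM inside, but only 3 were clear of its ends by more than counting error, and the range rests on 9 samples, so wrong labels stay open. Transcription from or through an insertion was not tested.

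Among the 54 levels tested in the 6 libraries labelled tt8, 4 had a library far from the others, where chance gives about 1 in 20. EGL3 was at 2.32 CPM in tt8-8 (next 5.80). In tt8-7, MYB12 was at 21.3 CPM (next 11.9), LBD41 at 409 CPM (next 515) and PGIP1 at 90.5 CPM (next 74.9).

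The libraries labelled tt8 and those of ttg1 differed at 9 genes in the direct test, and at 0 with the compared libraries fitted alone. A loss of TT8 was not established in the former. The log2 differences were 8.87 for LDOX, 8.26 for GSTF12, 8.15 for UGT79B1, 6.18 for 5MAT, 4.06 for AT4G04750, 2.56 for TTG2, 1.68 for AT3G14880, −2.23 for AT3G61198 and −2.85 for AT3G57950. The small RNA features that were left out of the tests held 0.0204% of the counts in ttg1-23, the highest share, against 0.0073% and 0.0072% in the Col-0 files.

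The comparison of regulators with enzymes called 0 genes in edgeR (884 at an unadjusted p under 0.05, and 1 in DESeq2), and with 0 calls every split gives as many, so the 100 of 100 drawn splits of the 14 libraries into 8 and 6, out of 3003 possible, decide nothing about chance. The highest other split called 3079 genes, and the others with any call gave 910 and 2750. These 3 splits kept ban-6, tt5-4, tt8-7, tt8-8, ttg1-23 and ttg1-24 on 1 side, the libraries with negative values on the first component, which points to a structure of the samples.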

How the results depend on the processing

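The Col-0 files as 2 samples and the surrogate variable were alternatives chosen after the data were seen. No named gene and no list reversed its direction. Over 939 runs of 65 calls at named genes the call held in 650 and was lost in 289. A gene called in several comparisons counts in each. Over 548 runs of 36 list calls the call held in 508 and was lost in 40. The line-end term lost 56 of 65 calls at named genes, the compared libraries alone 46 of 65 and thinned counts 40 of 65. Col-0 had Windows line ends, and of the mutant libraries only 2, both labelled tt8, had them too. The line-end term thus rests on the tt8 libraries and largely overlaps the difference from Col-0. Calls lost with that term cannot tell a batch from a loss of precision. RLE size factors lost 3 and the Col-0 files as 2 samples 0. A fit without a filter lost 18, and Windows files alone lost 15 with 0 held. Most other losses came with 1 library left out, chiefly in the groups of 2 alleles. Numbers of changed genes moved far more, and the cause was not tested except where fewer samples or counts entered. Values follow for tt8, ttg1, tt3, tt5, tt1 and ban against Col-0 in that order, from 458, 323, 125, 51, 322 and 118 genes. RLE size factors and the stricter filter kept all 6 within 1.5 times. Without a filter they were 289, 148, 58, 33, 168 and 61. Thinned counts gave 68, 57, 19, 16, 61 and 19, so depth limited how many genes passed in these 6 comparisons. With the line-end split as a term they were 34, 14, 10, 12, 22 and 14, and Windows files alone gave 0 for tt8. The libraries compared alone gave 0 for ttg1, tt5, tt1 and ban, 489 for tt3 (41.9% higher where 80.8% had been, and 25 shared with the 125), and 554 for tt8, of which 212 were higher and 342 lower, where 65.3% had been higher. The Col-0 files as 2 samples gave 4347, 2987, 2514, 865, 2229 and 1845, and the 458 genes of tt8 were among the 4347. The surrogate variable gave 984, 2253, 306, 287, 1038 and 476, and DESeq2 1481, 1510, 1022, 387, 1080 and 752. With each library left out in turn the ranges were 254 to 500, 30 to 375, 23 to 139, 19 to 61, 52 to 353 and 26 to 932. The libraries that moved a number by over 1.5 times were tt8-9 (254), tt8-10 (265), tt8-11 (261), tt8-12 (261), ttg1-24 (30), tt3-3 (23), tt3-4 (34), tt5-3 (19), tt5-4 (25), tt1-4 (52), ban-6 (932) and ban-7 (26). For tt8 against ttg1, 9 genes became 23 with thinned counts, 4 with the line-end term, 95 with the Col-0 files as 2 samples, 256 with the surrogate variable, 624 in DESeq2 and 0 with the compared libraries alone, and from 0 to 311 with a library left out (311 without tt8-7, 174 without ttg1-23 with 14.4% higher where 77.8% had been, 5 without tt8-9, 0 without ttg1-24). For regulators against enzymes DESeq2 gave 1 and every other run 0. The 5 late anthocyanin genes lower in ttg1 became 7 with the Col-0 files as 2 samples, 7 with the surrogate variable, 7 in DESeq2, 3 with thinned counts, 0 with the line-end term or the compared libraries alone, and 0 to 5 with a library left out, with 0 without either ttg1 library. The 36 list calls became 55 without a filter. They became 0 with an estimated correlation, a setting that the 548 runs do not include. The 11 genes low in 1 library became 26 at a threshold of 10%. No paired analysis was possible because the labels number only the Col-0 files, and the numbers of the mutant libraries merely follow their order of deposit. The alternative without organelle genes was not run, since the files list none.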

Other observations

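The test of the late anthocyanin list along the first component and every gene named here were chosen after the values were seen.

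Single genes that stood apart in 1 library are given as values, with no test of any group of genes and no count over the others that stood apart. In tt8-7, where 33 genes stood apart, 3 bHLH genes were high: BHLH100 was at 602 CPM (other samples 1.65 to 203), bHLH38 at 215 CPM (median of the others 10.7) and bHLH39 at 202 CPM (3.64 to 99.2), while the ferritin gene FER3 was low at 7.15 CPM (16.1 to 43.5) and the superoxide dismutase gene CSD2 was low at 7.50 CPM (15.5 to 85.9). In ttg1-24, which stood at least 2-fold above every other sample at 143 genes, 3 cytochrome P450 genes among them were CYP79B2 at 1270 CPM (224 to 605), CYP71A13 at 514 CPM (10.3 to 247) and CYP71A12 at 197 CPM (5.24 to 64.2). In tt1-4, 88 genes stood above every other sample, among them the storage protein genes CRA1 at 6640 CPM (25.7 to 1320) and SESA5 at 5710 CPM (6.50 to 253) and the dehydrin gene RAB18 at 1370 CPM (83.3 to 682). In tt3-3 the small heat shock genes HSP17.6II at 76.9 CPM (3.43 to 30.7), HSP18.2 at 46.8 CPM (3.86 to 22.6) and HSP21 at 22.5 CPM (0.997 to 7.82) were high.

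In ban-6, where 63 genes stood apart, OLEO1 at 12.2 CPM (other samples 30.0 to 1950), CRC at 17.7 CPM (40.6 to 6180) and the heme pathway gene HEMA2 at 10.2 CPM (52.7 to 369) were below every other sample, and the aquaporin genes TIP2;2 at 111 CPM (2.44 to 54.4) and TIP2;3 at 32.6 CPM (0.0626 to 6.58) above. Also in ban-6, AT2G43050 was at 16.4 CPM (0.264 to 0.871) next to the lost IBH1 (AT2G43060) on chromosome 2. In ban-7, where 59 genes stood apart, the squalene epoxidase gene SQE3 was at 691 CPM (63.8 to 118) and the plastid sigma factor gene SIG2 at 67.4 CPM (9.56 to 13.8), while the endodermal gene CASP1 was at 2.57 CPM (median of the others 27.4). In Col-0, BBX14 was at 2.43 CPM (0 to 0.0484).

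Late anthocyanin transcripts differed between libraries of 1 locus, and a hypothesis is that they follow the position of a library on the first component. Over the 15 samples other than ttg1, the median of the late list had r = 0.65 with the component built without its genes (95% interval 0.20 to 0.87, permutation p = 0.011, adjusted over 2 relations 0.021). The rho was 0.65 (permutation p = 0.011), and r was 0.55 over 13 samples without ban-6 and Col-0. The permutations shuffled samples and compared no random lists, so they do not single out late anthocyanin genes. The lower bound of the interval falls short of the 0.3 set for the test, so the relation may be weak and stays open, and the libraries tt8-7 and tt8-8, with the lowest late medians among those labelled tt8, both lay at negative values of the component.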
